A study of Mus musculus with 8 samples.

How the data were processed

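RNA sequencing was performed on 8 samples of mouse dendritic cells, 4 transfected with a control siRNA (si-nc) and 4 with an siRNA against Suclg2 (si-Suclg2). Per the labels' protocols, bone marrow cells of C57/BL6 mice were grown for 6 days in GM-CSF plus IL-4, followed by 24 hours of lipopolysaccharide (LPS). CD11c-positive cells were then selected with magnetic beads and kept for 9 days on spleen stroma before transfection. Total RNA was taken with TRIzol and sequenced on an Illumina HiSeq platform, per the labels' protocols. The time between transfection and collection, the siRNA sequences and the origin of the replicates (separate cultures, animals or transfections) are not given in the sources used here.

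The values came from one table of 15465 genes that the authors deposited, with a value per gene and sample, a log2 fold change, and p-values and q-values. Per the submitters' processing notes the genome builds were GRCm38.p4 and mm10. The aligner, the counting tool and the gene annotation are not given in the sources used here. Per the file headers, the p-value and q-value are from DEGseq. The deposited log2 fold change is positive where the si-Suclg2 values are higher. The header does not state this sign, which was read from the values (-0.859 for Suclg2 and 6.894 for Slc13a3). The header does not name the unit of the per-sample values. They were treated as FPKM (fragments per kilobase of transcript and scaled to the fragments of the library), as made by the authors, because of how they behave. The number of reads implied by each deposited p-value and fold change, divided by the gene's mean value, rose with transcript length (Spearman rho = 0.87 across 4700 genes, which are not independent replicates). After division by length it was nearly constant, with medians of 171.8 to 174.1 over 8 length classes. If the values are FPKM, this corresponds to a depth of about 21.6M reads per library; no count or depth is stated, so no counting interval is given. The behaviour by length does not tell FPKM from TPM, which is also scaled by length. The values summed to unequal totals, between 506242 and 539290 per sample, which TPM over a full set of genes would not. As the test for a table without counts had been laid down in advance for FPKM, TPM or CPM alike, the inferred unit did not change the choice of test.

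In 22 rows the gene symbol had been turned into a date by a spreadsheet, and the current symbol was restored through the gene ID. One symbol stood in 2 rows, and both rows were kept. The table listed 0 mitochondrially encoded genes, so these were not analysed here.

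Genes with a mean FPKM of at least 1 in at least one group were tested (10176 genes). The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean trend in the prior variance, group as the only term, and Benjamini-Hochberg adjustment at 0.05. Every log2 fold change below is si-Suclg2 minus si-nc on this scale, which understates the change of genes with low values. Folds stated as such are ratios of mean FPKM. The siRNA target was also tested with a two-sided exact permutation test over the 70 assignments of 4 and 4 samples, whose smallest possible p is 0.0286. On simulated data for this comparison, built on the 10176 genes with 200 changed and no division between replicate numbers, the test found 82.1% of log2 changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2, and called 0.13% of unchanged genes. With such a division simulated, as the samples show, it found 77.6%, 100% and 100% and called 0.02%, and with the replicate block 91% of changes of 0.5 were found. Apart from the division the simulated samples were independent, and the 200 changed genes were far fewer than the genes called in the data. The shares of unchanged genes called here therefore do not give the false calls among the real ones.

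A set of 21 lists of genes by function and 11 lists of cell type markers was fixed before the data were examined; 720 of their 771 entries were found in the table. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the function lists and over the marker lists separately. Named genes were chosen by a rule fixed at the same time. They are Suclg2, Lactb, Suclg1 and Sucla2; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted genes and pseudogenes; and up to 4 members of each list with the smallest p. The filter for the gene-wide test was not part of that plan and was taken from the rule for named genes.

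Samples of both groups carry the numbers 1 to 4, which the labels do not tie to a shared culture or day. Deviations from the group means, across genes, correlated between same-numbered samples of the 2 groups with r of 0.40 to 0.55, above the 0.1 set for treating the numbers as pairs, so a fit with the number as a replicate block is given where it changes a result. Only 3 of the 8 libraries correlated best with their own number, because numbers 1 and 2 resembled each other, as did 3 and 4 (r of 0.35 to 0.50 within a group). Replicates 1 and 2, or 3 and 4, of one group differed by an SD of 0.06 to 0.12 in log2 ratio over 756 genes with a mean of at least 100 FPKM, and samples across that divide by 0.189 to 0.245. They were kept as 8 samples. P-values therefore measure only the spread between these samples, which may be technical.

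Alternatives planned before the data were examined were the replicate block, quantile normalization, trimmed-mean scaling, a prior without trend, other filters and pseudocounts, leaving out each sample, a fold change minimum, the authors' deposited q-values and other set tests (camera with an estimated correlation, and limma's fry). Alternatives chosen after seeing the data were a common column sum, a block for the divide between numbers 1 and 2 and numbers 3 and 4, means of those pairs, each pair of numbers alone, a correction for transcript length and GC content, a stroma score as covariate and a minimum list size. Coordinates are from GENCODE annotation of GRCm38; the deposited table gives none. The text describes only some of the 128 genes that the rule names, and one of them is not reported here.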

Results

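Gene expression was measured by RNA sequencing in dendritic cells that had been matured with LPS and then kept on spleen stroma, a coculture that yields regulatory dendritic cells. The series title asks about Suclg2, which encodes the GTP-specific beta subunit of the mitochondrial succinyl-CoA ligase, and about the mitochondrial protein Lactb. The design held 4 si-nc samples and 4 si-Suclg2 samples. Summed FPKM per sample ran from 506242 to 539290, and between 9903 and 10177 genes reached 1 FPKM in a sample.

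Suclg2 was lower in all 4 si-Suclg2 samples than in any si-nc sample. Its level (gene ID 20917; GRCm38 chromosome 6, 95473009 to 95718800, minus strand, protein-coding) was 4.59 ± 0.122 FPKM (SD, n = 4) with si-nc and 2.48 ± 0.252 FPKM (SD, n = 4) with si-Suclg2, so that 53.9% remained. The log2 fold change was -0.69 ± 0.066 (SE; limma adjusted p = 8.84e-05), and the two-sided exact permutation test gave p = 0.0286, the smallest that this design allows. Suclg1, the alpha subunit, was at 31.8 ± 0.929 and 32.4 ± 0.790 FPKM, and Sucla2, the ATP-specific beta subunit, at 14.8 ± 1.31 and 15.4 ± 0.713 FPKM (SD, n = 4 each). Lactb was at 12.4 ± 1.13 FPKM with si-nc and 12.2 ± 0.314 FPKM with si-Suclg2. None of these 3 genes passed the test (limma adjusted p = 0.689, 0.571 and 0.856). The measurement is of mRNA only and holds no information on succinylation.

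**Figure D1:**
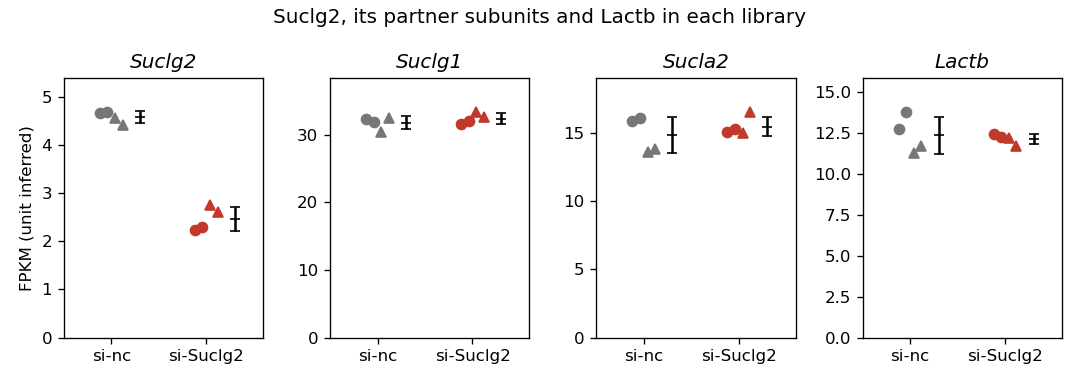
FPKM (unit inferred) of Suclg2, Suclg1, Sucla2 and Lactb on linear axes that start at 0, one point per sample (circles, numbers 1 and 2; triangles, numbers 3 and 4), with mean and SD in black. Suclg2 fell from a mean of 4.59 to 2.48 FPKM without overlap, while the groups overlap for the other genes.

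The gene with the largest rise was Slc13a3, which encodes a sodium-coupled dicarboxylate transporter. It went from 0.635 ± 0.122 FPKM with si-nc to 75.5 ± 22.0 FPKM with si-Suclg2 (SD, n = 4 each; log2 fold change 5.51 ± 0.178 SE, limma adjusted p = 3.91e-07). The scavenger receptor Marco rose 11.3-fold, from 20.8 ± 3.18 to 234.9 ± 17.9 FPKM, and the inhibitory lectin Siglece rose 13.3-fold, from 2.80 ± 0.735 to 37.2 ± 4.85 FPKM. The acute-phase gene Saa3 rose 7.71-fold to 2612 ± 549 FPKM. Susd2, Lcn2, Cd300e, Tarm1, Fpr1, the chemokine gene Ccl7, the inducible nitric oxide synthase gene Nos2 and the cytokine-signalling inhibitor Socs3 completed the 12 largest rises, with log2 fold changes from 2.89 down to 1.79. The largest fall was in Klk1b11, from 202.6 ± 24.8 to 28.7 ± 6.37 FPKM (log2 fold change -2.79 ± 0.146 SE, limma adjusted p = 2.92e-06). It belongs to a family of similar kallikrein genes among which reads can be shared, so its value is uncertain. Cd28 fell from 10.8 ± 0.725 to 1.93 ± 0.348 FPKM, Cd4 from 9.63 ± 2.79 to 2.14 ± 0.225 FPKM, and the maturation marker Cd83 from 56.5 ± 10.1 to 17.4 ± 1.43 FPKM. Lrrc14b, Mamdc2, the monoacylglycerol lipase gene Mgll, Mcoln3, Gpr162, Adgre4, the fatty acid binding protein gene Fabp4 and the iron exporter gene Slc40a1 made up the rest of the 12 largest falls, with log2 fold changes from -1.76 to -1.37.

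In all, 2740 of 10176 genes passed adjusted p 0.05 in limma, 1221 of them higher and 1519 lower with si-Suclg2. Among them, 53 rose and 50 fell by at least 1 on the log2 scale. Groups did not overlap for 29.6% of the genes tested, against 2.86% by chance if all 8 samples were independent. The likeness of numbers 1 and 2, and of 3 and 4, puts that in doubt, so the excess over chance is uncertain. With the replicate block 4126 genes passed, 1832 higher and 2294 lower. The share of higher genes among those called was 44.6%, and 58.5% after trimmed-mean scaling. Numbers 1 and 2 alone gave 3181 genes and numbers 3 and 4 alone 3311, and all 2740 genes had the same sign in both, which selection on the pooled samples favours. When the means of numbers 1 and 2 and of numbers 3 and 4 were taken as the replicates, 279 genes passed.

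**Figure D2:**
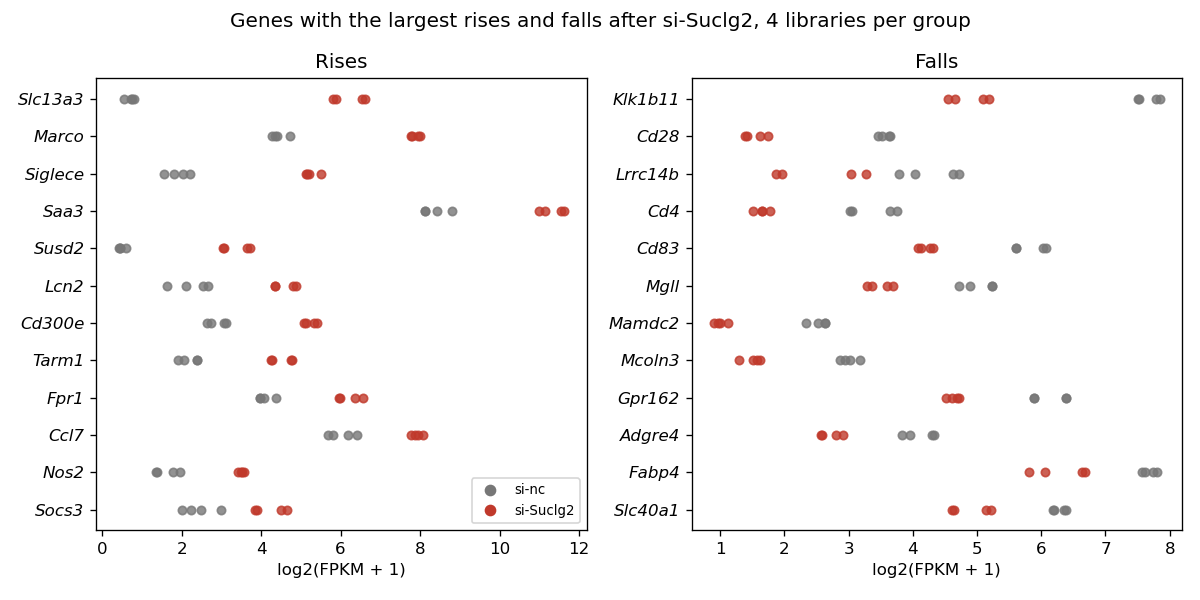
The 12 largest rises and the 12 largest falls, with log2(FPKM + 1) on the horizontal axis and one point per sample (grey, si-nc; red, si-Suclg2; 4 samples each). By the rule that chose them, the groups do not overlap in any of these genes; Slc13a3 had the largest rise, at 5.51, and Klk1b11 the largest fall, at -2.79.

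Of the 21 function lists, 9 were called by camera with the preset correlation, 6 higher and 3 lower with si-Suclg2. With the correlation estimated from the data, 0 of the 21 passed; the estimated values follow beside each called list. With means of pairs of numbers as replicates, camera with the preset correlation kept all 9 calls, but limma called far fewer members of these lists. There, 2 interferon, 6 glycolysis, 2 hypoxia and 6 cytokine and chemokine genes rose, as did 1 antioxidant and 1 oxidative phosphorylation gene, with 0 falls on these 6 lists. Lysosome and phagocytosis genes had 2 rises and 3 falls. Cholesterol and ribosomal protein genes had 0 falls, and 4 and 6 at an unadjusted p under 0.05. A different question, whether the genes of a list move on balance one way without regard to other genes, was put with fry and the replicate block. Of the 9 lists called by camera, 7 passed it, and cholesterol biosynthesis (adjusted p = 0.0622) and oxidative phosphorylation (0.0997) did not. Of the others, NF-kB targets (0.00774) and tolerogenic genes (0.0123) passed as higher, and apoptosis and p53 (0.0123) and MHC class II genes (0.0198) as lower. Of the 41 type I interferon response genes tested, 25 rose, 0 fell and 16 did not pass (30 rose adjusted over the list alone). The median log2 fold change was 0.26 (camera adjusted p = 1.49e-12; adjusted p = 0.203 with an estimated correlation). Oasl1, an antiviral gene, rose from 165.2 ± 11.8 to 298.3 ± 6.63 FPKM, Isg20 from 130.9 ± 7.31 to 190.2 ± 1.08 FPKM, and the signal transducer Stat2 from 159.8 ± 9.25 to 207.6 ± 4.80 FPKM. Of 20 glycolysis genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 1.44e-11; adjusted p = 0.186 with an estimated correlation). The pyruvate kinase gene Pkm rose 1.82-fold to 723.3 ± 35.6 FPKM, the enolase gene Eno1 1.74-fold to 377.4 ± 38.3 FPKM and the aldolase gene Aldoa 1.64-fold to 965.5 ± 77.4 FPKM. Of 18 hypoxia response genes, which share members with the glycolysis list, 10 rose and 2 fell, the same numbers as adjusted over the list alone (median 0.27, camera adjusted p = 0.00105; adjusted p = 0.203 with an estimated correlation). The hypoxia list had 1 fall when any single sample other than si-nc replicate 3 or si-Suclg2 replicate 1 was left out. The glycolysis list had 0 falls without si-nc replicate 1 or 2 or si-Suclg2 replicate 2, 3 or 4. The prolyl hydroxylase gene P4ha1 rose from 45.5 ± 1.55 to 66.2 ± 2.52 FPKM.

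Of 22 inflammatory cytokine and chemokine genes tested, 11 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000494; adjusted p = 0.0988 with an estimated correlation). Ccl5 rose 2.38-fold to 10070 ± 203 FPKM, Ccl12 2.77-fold to 278.5 ± 20.5 FPKM and Tnf 1.61-fold to 24.9 ± 2.07 FPKM. Of 37 NF-kB targets, 12 rose and 6 fell (13 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0706), but passed with the replicate block (adjusted p = 0.0276), without si-nc replicate 2 (0.0344) and without si-nc replicate 4 (0.0497). It also passed with a common column sum, the stroma score, pair means, either pair of numbers alone, the division as a block, and length and GC correction with the replicate block (0.0209 to 0.0476). With an estimated correlation the NF-kB adjusted p was 0.393. The falls on it were 3 without si-nc replicate 1, 2 or 3. Nfkbiz, an NF-kB co-regulator, rose from 6.01 ± 0.342 to 17.2 ± 2.21 FPKM, while Cd83, also on the list, fell. Of 34 tolerogenic and regulatory genes tested, 11 rose and 9 fell (12 and 9 adjusted over the list alone), with a camera adjusted p of 0.1001, and of 0.0413 with the replicate block. It was 0.0158 with numbers 3 and 4 alone, 0.0421 with the stroma score, 0.0444 with the division as a block, 0.0771 with means of pairs of numbers and 0.234 with an estimated correlation. Hmox1, the heme oxygenase gene, rose from 224.0 ± 24.7 to 386.8 ± 13.0 FPKM, whereas Entpd1, an ectonucleotidase gene, fell from 85.7 ± 8.19 to 40.5 ± 1.05 FPKM and the receptor ligand gene Gas6 from 140.2 ± 5.82 to 71.6 ± 8.75 FPKM.

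Dendritic cell maturation and co-stimulation genes moved both ways, with 5 of 21 higher and 7 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.594). The co-stimulatory gene Cd86 fell from 57.8 ± 2.92 to 40.7 ± 4.24 FPKM, while Tnfsf9 rose from 2.77 ± 0.327 to 4.50 ± 0.286 FPKM. Of 12 MHC class II presentation genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.796); the median was 0.02 and the mean -0.22. The invariant chain gene Cd74 fell from 883.1 ± 67.0 to 505.8 ± 59.6 FPKM, H2-Aa from 210.5 ± 29.6 to 109.5 ± 31.0 FPKM and H2-Eb1 from 66.3 ± 11.3 to 34.0 ± 11.0 FPKM. Marchf1, a ubiquitin ligase gene that acts on MHC class II, rose from 29.3 ± 0.184 to 36.5 ± 0.303 FPKM. Of 21 MHC class I presentation genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.237). With the replicate block 7 of these rose and 4 fell, and 1 rose without si-nc replicate 1, si-Suclg2 replicate 3 or si-Suclg2 replicate 4. Class I genes had 1 fall when any single sample other than si-Suclg2 replicate 2 was left out. Of the MHC class II genes 5 fell with the block, and 5 after quantile normalization, and 1 rose without si-nc replicate 1 or 2 or si-Suclg2 replicate 3 or 4.

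Lysosome and phagocytosis genes were lower as a list, with 20 of 36 lower and 4 higher (22 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.00217; adjusted p = 0.186 with an estimated correlation). The lysosomal hexosaminidase gene Hexa fell from 564.1 ± 27.4 to 336.0 ± 15.3 FPKM and Clec7a, the beta-glucan receptor gene, from 307.0 ± 23.1 to 123.3 ± 3.98 FPKM. The members that rose included Marco and the Fc receptor gene Fcgr1, which rose from 354.0 ± 7.38 to 517.2 ± 22.0 FPKM. Of 20 cholesterol biosynthesis genes, 0 rose and 5 fell (8 adjusted over the list alone; median -0.16, camera adjusted p = 0.00374; adjusted p = 0.561 with an estimated correlation), among them Sqle and the regulator gene Srebf2. With the replicate block 8 fell. The call was lost with numbers 3 and 4 alone (median -0.07, adjusted p = 0.2996). Of 32 cytosolic ribosomal protein genes, 0 rose and 9 fell (10 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00217; adjusted p = 0.732 with an estimated correlation). The falls numbered 21 after quantile normalization, 6 after trimmed-mean scaling, and 18 with the replicate block or after length and GC correction. Reads of ribosomal protein genes can be shared with their pseudogenes.

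Oxidative phosphorylation genes encoded in the nucleus had a median of 0.10, with 5 of 46 higher and 0 lower (3 higher adjusted over the list alone; camera adjusted p = 0.00261; adjusted p = 0.732 with an estimated correlation). The cytochrome c gene Cycs rose from 29.2 ± 1.37 to 42.1 ± 2.83 FPKM. The list was no longer called after quantile normalization (adjusted p = 0.169) or with a stroma marker score in the model (median 0.02, adjusted p = 0.443). The rises numbered 16 with the block, 10 after trimmed-mean scaling or without si-nc replicate 4, 9 without si-Suclg2 replicate 1, and 3 without si-nc replicate 1 or 2 or si-Suclg2 replicate 3 or 4. After quantile normalization 3 rose and 1 fell. Of 26 antioxidant response genes, 11 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.14, camera adjusted p = 0.00836; adjusted p = 0.608 with an estimated correlation), and this call too was lost after quantile normalization (adjusted p = 0.181), and with numbers 1 and 2 alone (median 0.05, adjusted p = 0.123). With the replicate block 5 of these genes fell. The peroxiredoxin gene Prdx1 rose from 1051 ± 42.6 to 1576 ± 74.4 FPKM, while Nfe2l2, which encodes the regulator Nrf2, fell from 175.6 ± 5.83 to 125.5 ± 8.89 FPKM. Of 23 succinyl-CoA and TCA cycle genes, 3 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.494), the falls being Suclg2 itself and the succinate dehydrogenase gene Sdha, at 88.4 ± 0.511 and 74.4 ± 3.88 FPKM. With the replicate block 6 rose and 5 fell.

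**Figure D3:**
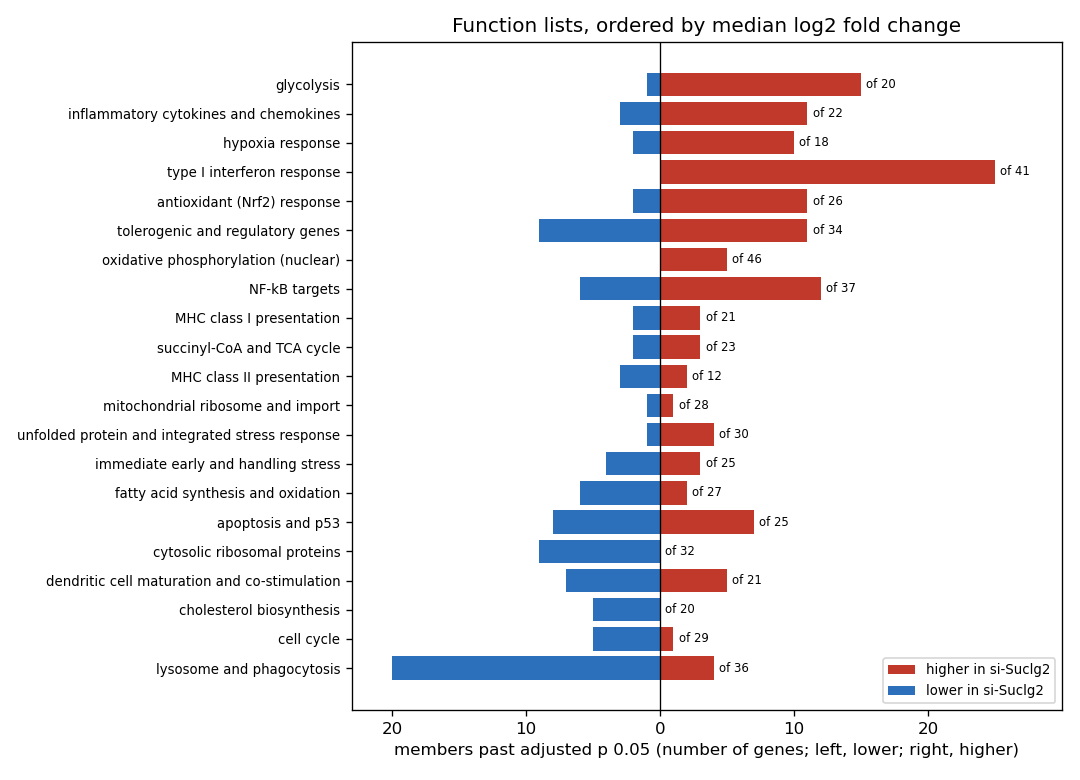
Number of members of each function list past adjusted p 0.05, with higher genes to the right and lower genes to the left of 0 and the number tested beside each bar. The type I interferon list has 25 higher and 0 lower of 41, and the lysosome and phagocytosis list 4 higher and 20 lower of 36.

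The other function lists were not called. Of 25 apoptosis and p53 genes, 7 rose and 8 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.594). Casp1 rose from 66.9 ± 8.09 to 107.7 ± 7.36 FPKM, while the pro-apoptotic gene Bax fell from 131.5 ± 5.45 to 95.4 ± 3.75 FPKM. Of 29 cell cycle genes, 1 rose and 5 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.259), and without si-nc replicate 3 the list was called (adjusted p = 0.0124), with 10 falls, as it was with numbers 1 and 2 alone (adjusted p = 0.0209, with 13 falls); the adjusted p with all samples and an estimated correlation was 0.8655. Its falls numbered 13 with the replicate block, 0 without si-Suclg2 replicate 4, 1 without si-nc replicate 2 or si-Suclg2 replicate 3, 2 without si-nc replicate 1 or si-Suclg2 replicate 2, and 3 without si-nc replicate 4. Fatty acid synthesis and oxidation genes had 2 of 27 higher and 6 lower, as adjusted over the list alone (camera adjusted p = 0.562). The mitochondrial ribosome and import list had 1 of 28 higher and 1 lower, and 0 adjusted over the list alone (camera adjusted p = 0.494). On that list 0 rose and 0 fell without si-nc replicate 1 or 3 or si-Suclg2 replicate 1, 2 or 3. The unfolded protein and integrated stress response list had 4 of 30 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.783). Immediate early and handling stress genes had 3 of 25 higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.928). With the replicate block the falls were 13 for apoptosis and p53, 7 for immediate early genes and 7 for the unfolded protein list, which had 7 rises, and 4 genes each rose on the fatty acid and mitochondrial ribosome lists. Fatty acid falls were 3 after trimmed-mean scaling or without si-nc replicate 1, 2 or 4. Rises on the unfolded protein list were 1 without si-nc replicate 1 or 2 or si-Suclg2 replicate 4 and 2 without si-nc replicate 3 or si-Suclg2 replicate 3, and its falls 4 without si-nc replicate 3 and 5 without si-Suclg2 replicate 1.

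Markers of dendritic cells and of other cell types that the cultures could hold were tested in the same way. Of 11 lists, 10 had a member tested, and 0 were called. Macrophage and monocyte genes were abundant in both groups, with Lyz2 at 10380 ± 1140 and 7455 ± 714 FPKM and Apoe at 9883 ± 1393 and 6433 ± 601 FPKM. Of 16 such genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.780), with Adgre1 higher at 333.1 ± 37.6 and 596.7 ± 52.4 FPKM. The rises were 5 with the replicate block, and the falls 2 without si-nc replicate 3 or 4. Of the 14 conventional dendritic cell genes fixed, 9 had values and only 5 reached the filter. Among 5 conventional dendritic cell genes tested, 0 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.703), these being Itgax, from 20.2 ± 2.84 to 12.6 ± 0.958 FPKM, and Clec10a, from 12.6 ± 4.62 to 4.18 ± 0.136 FPKM. Fibroblast or reticular stroma genes had 1 of 8 lower and 0 higher (0 adjusted over the list alone), with a median of -0.69 and a camera adjusted p of 0.0924. This list passed with the replicate block (adjusted p = 0.0229), without si-nc replicate 3 (0.0138) and without si-Suclg2 replicate 1 (0.0171), with 7, 4 and 6 of the 8 genes lower, and 0 were lower when any other single sample was left out. It also passed after trimmed-mean scaling, with either pair of numbers alone, pair means, the division as a block, and length and GC correction with the replicate block (0.0101 to 0.0401). With an estimated correlation the adjusted p was 0.804. Col1a1 was at 5.86 ± 2.55 FPKM with si-nc and 3.21 ± 1.52 FPKM with si-Suclg2 (SD, n = 4 each; limma adjusted p = 0.122, and 0.00694 with the replicate block), lower with si-Suclg2 at each of the 4 numbers. Stroma marker levels were far below those of the macrophage genes in both groups. Of the T cell and NK cell list only Cd4 and Il7r were tested, and both fell (2 adjusted over the list alone; camera adjusted p = 0.0768, and 0.0229 with the replicate block; adjusted p = 0.309 with an estimated correlation). It was also called without si-nc replicate 3 (adjusted p = 0.0274) and without si-Suclg2 replicate 1 (0.0471), and under those settings and the filter of 5 FPKM (0.00708 to 0.0469). The 7 members of this list with values had a median of 0.045 FPKM with si-nc and 0.035 FPKM with si-Suclg2. All but Cd4 and Il7r stayed below the filter of 1 FPKM in both groups, so these falls do not show a loss of T or NK cells. Plasmacytoid dendritic cell genes had 4 of 5 higher, as adjusted over the list alone (camera adjusted p = 0.0924). The changes of these 4 genes were small, at 1.12-fold to 1.46-fold, and do not show more plasmacytoid cells. The rises were 1 without si-nc replicate 2 or si-Suclg2 replicate 2 or 4 and with the stroma score, and 2 without si-nc replicate 1 or 4 or si-Suclg2 replicate 3. This list was called with the filter of 5 FPKM (adjusted p = 0.0469) and with numbers 3 and 4 alone (0.0398). With an estimated correlation its camera adjusted p was 0.3085. Endothelium had 1 of 3 genes higher, as adjusted over the list alone, and neutrophil genes 1 of 3 higher (1 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.751 for both lists. The endothelial gene did not pass without si-nc replicate 3 or 4 or si-Suclg2 replicate 1, 3 or 4, nor the neutrophil gene without si-nc replicate 1, 2 or 3 or si-Suclg2 replicate 3 or 4. Fry with the replicate block called the T cell and NK cell list (Cd4 and Il7r alone) as lower (adjusted p = 0.00022). Of the other marker lists, it called plasmacytoid and neutrophil genes as higher (adjusted p = 0.0261 each). The single genes tested for mast cells and basophils, eosinophils, and the erythroid and megakaryocyte lineages did not pass, and 0 of the B cell and plasma cell genes reached the filter.

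Samples numbered 1 and 2 differed from those numbered 3 and 4 in both groups, a division that the labels do not mention. In a model with group and this division, 3778 genes passed for the division, 1741 higher and 2037 lower in numbers 3 and 4. The divide runs across both groups alike, so it does not coincide with the siRNA.

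**Figure D4:**
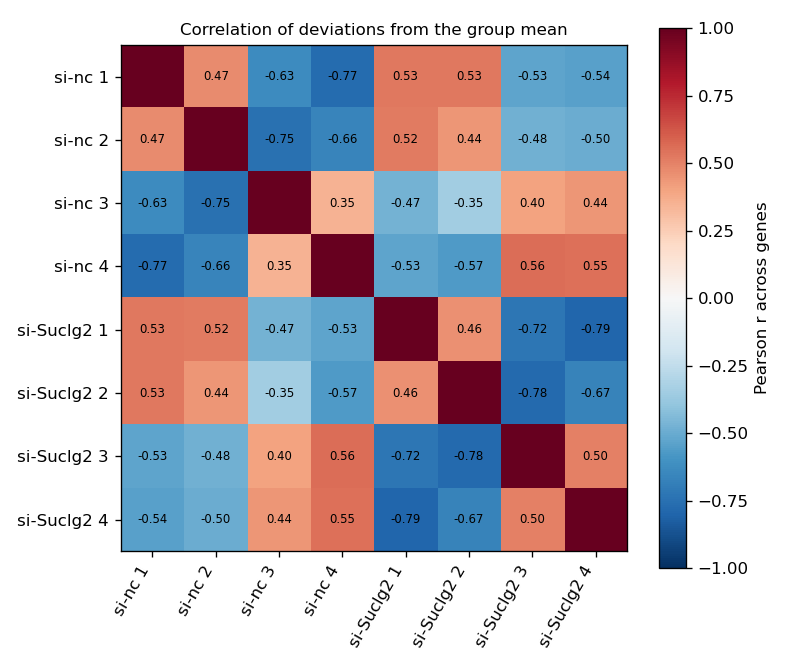
Pearson correlation across genes between samples of their deviations from the group mean in log2(FPKM + 1). Numbers 1 and 2 correlate positively with each other within and across groups, as do 3 and 4, and same-numbered samples of the 2 groups lie between 0.40 and 0.55.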

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

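The test of transcript length and GC content and the test on macrophage markers below were chosen only after the division between samples had been seen, and the bound used for length and GC content was worded after its result. Among 256 groups of 4 samples (each named gene in each siRNA group), 4 held a sample far from the others, measured as its gap to the nearest sample divided by the range; chance alone marks about 1 in 20 groups. All 4 were si-nc groups. Hspe1 was at 85.0 FPKM in si-nc 4 and at 72.4 to 72.9 in the others (0.956 of the range). S100a8 was at 1.79 FPKM in si-nc 4 and at 0.90 to 1.02 in the others (0.865), and Tomm40 at 18.6 in si-nc 4 and 17.3 to 17.5 in the others (0.868). Pdia3 was at 179.1 FPKM in si-nc 1 and at 197.2 to 200.2 in the others (0.858).

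The division of numbers 1 and 2 from numbers 3 and 4 follows no group that the design names. Of explanations that the design offers, only a carry-over of stroma was tested. The effect of the division fell with transcript length (Spearman rho = -0.44 across genes), yet 2337 of the 3778 genes called for the division were also called in the same direction after each library was corrected for length and GC content (3119 in all), which argues against such a trend as the whole cause. With a stroma marker score in the model 1201 of the 3778 were called in the same direction (1267 in all), so a lower carry-over of stroma in numbers 3 and 4 may contribute. That score itself differs between the 2 sides of the division, and a term that overlaps with it costs power. The test on macrophage and monocyte markers left open whether less stroma was the only difference. Of 15 such markers 11 were called higher and 1 lower (Mrc1) in numbers 3 and 4, and a single gene excludes nothing. Vcan, also called lower (-0.46), was left out after its value was seen because stroma expresses it too, and with it the 2 falls would have argued against stroma as the only difference. The stroma scores do argue against it. Within a group, pairs across the divide differed by an SD of 0.189 to 0.245 in log2 ratio and other pairs by 0.06 to 0.12. Yet si-Suclg2 1 and 2 scored 0.299 and -0.316 (SD 0.081), and 2 and 3 scored -0.316 and -0.466 (0.189). Si-nc 3 and 4 scored -0.301 and 0.196 (0.12), and 1 and 4 scored 0.548 and 0.196 (0.245). A difference in culture, RNA handling or sequencing batch stays open, since the labels record none.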

How the results depend on the processing

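The alternatives that use the common column sum, the division between numbers 1 and 2 and numbers 3 and 4, length and GC content, the stroma score or a minimum list size were chosen after seeing the data. The number of genes called, 2740 (1221 higher, 1519 lower), stayed within 1.5 times that value under other filters, pseudocounts and scalings and when any sample was left out (2127 to 2624 in all, 956 to 1176 higher, 1171 to 1448 lower). It moved further in these cases. The replicate block gave 4126 (1832 higher, 2294 lower), with 2738 of the genes shared in direction, and a block for the division 4534 (1995, 2539). Length and GC correction with the replicate block gave 4335 (1923, 2412). The authors' deposited q-values gave 7363 (2948, 4415) over all 15465 genes deposited, 6444 of them among the 10176 genes tested here. A fold change minimum of 1 on the log2 scale gave 103 (53, 50) by its construction, and means of pairs of numbers 279 (130, 149), with fewer samples. Where no construction is named, the cause was not tested.

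Suclg2 kept its direction and passed under every alternative that gave it a value except the fold change minimum, which its -0.69 does not reach, with log2 fold changes of -0.87 to -0.36 over the pseudocounts and -0.73 to -0.65 when any sample was left out. It fell below the filter of 5 FPKM. The number of function lists called, 9, was 0 with an estimated correlation, 7 to 11 otherwise, and 9 to 10 when any sample was left out. The number of marker lists called, 0, was 2 with the replicate block, trimmed-mean scaling, the filter at 5 FPKM, the division block, pair means, numbers 1 and 2 alone, and length and GC correction with the replicate block. It was 3 with numbers 3 and 4 alone and with fry and the replicate block, and 0 to 2 when any sample was left out (2 without si-nc replicate 3 or si-Suclg2 replicate 1). Apart from the lists NF-kB targets, tolerogenic and regulatory genes, stroma and T cell and NK cell, the replicate block changed no list's call; among the other named genes it added 10 calls and lost 0. Of the named genes, 1 changed sign with a call on either side: Pf4, at 0.10 without a call, was at -0.29 with numbers 1 and 2 alone. Sign changes of genes with no call on either side, such as Sucla2, Suclg1, Lactb and Kdr, were not counted. With pair means 63 named genes lost their call, and between 4 and 15 did when a sample was left out. The depth is not stated, so the precision of low values could not be set from counts. The alternative for a table without sample values was not needed.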

Other observations

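The test of scaling was settled after its result was seen, while the tests of lysosomal and p53 genes and of stroma and length effects on the list results were written down before; the 3 lists they bear on and the gene sets were chosen after the main comparison. Lysosomal genes not on the fixed list were lower as a set in si-Suclg2. Of 34 genes of the CLEAR network, a set of lysosomal genes controlled by TFEB, 19 fell, 0 rose and 15 did not pass, with a median log2 fold change of -0.24 (camera p = 4.28e-07, and p = 0.00614 with an estimated correlation). The falls included Gusb, Flcn, Clcn7 and the proton pump subunit gene Atp6v1c1, named after their values were seen. After length and GC correction 21 fell and 1 rose, and with pair means as replicates 2 fell. A lower CLEAR network response is a candidate explanation; fewer lysosomes or a shift in cell state were not tested.

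Of 23 p53 target genes not on the fixed list, 8 fell and 4 rose, with a median log2 fold change of -0.08. The falls were 4 without si-nc replicate 1 and 5 without si-nc replicate 2 or 3 or si-Suclg2 replicate 2 or 3. As a set they did not pass limma's camera (adjusted p = 0.115 over the 2 sets tested in this way). With fry and the replicate block, which compares a set with no other genes, it was lower on balance (adjusted p = 0.000567), so whether the falls of Bax and other p53 targets on the fixed list belong to a lower p53 response stays open.

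For the number of genes called, an arbitrary grouping is excluded only if all 8 samples can be exchanged freely: of the 35 splits into 4 and 4, 1 gave at least 2740 genes, the real one. The highest of the others, 1165 genes, was the split of numbers 1 and 2 from numbers 3 and 4, which points to a structure of the samples, and 33 splits gave 0. Among the 8 splits that part all 4 numbers, which are too few for a share under 0.05, the others gave 0 genes. For the number of function lists called, chance was not excluded. Of the 35 splits, 4 gave at least 9 lists, the real one included, and the highest of the others was 9. Among the 8 splits that part all numbers, 2 did, the real one included. The other splits with 9 lists kept 3 samples of one siRNA group with 1 of the other on each side. They hold part of the real contrast, so this count cannot decide whether chance gave the 9 lists. Splits with 2 samples of each group on either side gave at most 6.

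Interferon, glycolysis and cytokine lists were higher with si-Suclg2. A length and GC trend, scaling between libraries and less stroma are argued against as the whole cause. All 3 lists stayed called after length and GC correction (3 of 3) and with the stroma score in the model (3 of 3), and after quantile normalization (3 of 3, with a lowest median of 0.19). Trimmed-mean scaling and a common column sum shift the genes of a library nearly alike, so they hardly bear on a test against other genes. With an estimated correlation none of the 3 passed, so their calls stay open. Members of the interferon and glycolysis lists were correlated (0.297 and 0.309); those of the cytokine list were not (-0.004), and that form of camera also uses fewer degrees of freedom. A response to the siRNA itself, or to its sequence, was not tested, since the samples hold one siRNA treatment against Suclg2 as far as the labels say. That these changes follow from the loss of Suclg2 may be held only as a hypothesis.

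The effect of si-Suclg2 differed between numbers 1 and 2 and numbers 3 and 4 in 103 genes (limma interaction, adjusted p 0.05), 54 of them among the genes called. Of the 12 largest rises, Slc13a3, Susd2 and Cd300e were among the 103. Of the 12 largest falls, Klk1b11, Cd83, Cd4, Mgll, Gpr162, Fabp4 and Slc40a1 were. So were Cd86, Gas6, H2-Aa, H2-Eb1 and the glycolytic genes Gapdh, Tpi1 and Pgam1. In numbers 1 and 2 and in numbers 3 and 4, Klk1b11 had log2 fold changes of -2.38 and -3.21. Those of Slc13a3 were 5.20 and 5.81, of Cd83 -1.32 and -1.95, and of H2-Aa -1.16 and -0.78.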
